A study of Caenorhabditis elegans with 15 samples.

How the data were processed

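RNA was measured in dissected intestines of 5-day-old Caenorhabditis elegans, with 20 intestines per sample and 5 samples in each of 3 groups. The groups were wild type, gas-1(fc21) mutants, and gas-1(fc21) mutants that overexpress cest-2.2, called gas-1 cest-2.2 OE or OE here. Per the labels, worms grew on OP50 bacteria, total RNA was extracted from the intestines, and full-transcript libraries that keep no strand information were made by Smart-seq2.

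Per the labels, the authors used bcl2fastq 2.20 and kallisto 0.44.0 with genome build WBcel235, and the annotation release is not stated. The deposited files hold, per the file headers, estimated counts (expected counts, not normalized), TPM (transcript abundances scaled by length and to 1 common total per library) and transcript lengths (other values, in bases) for 61451 targets in each of the 15 libraries. The deposited transcript map names a gene for each target, but the targets in the count files carry only integers. These were read as line numbers of the map counted from 0. Under that reading the deposited length equalled the annotated length of 99.96% of 27233 non-coding transcripts in Ensembl release 115, and was at least the coding length in 99.54% of 29548 coding transcripts. With the map moved by 1 line the first share was 53.07% and the second was 60.13%. Gene identities rest on that reading. A deposited table by the authors gives, per the file headers, mean normalized counts per group (a signal scale), p-values, log2 fold changes and signed fold changes and test statistics (scores). Among its 4159 transcripts with all 3 group means above 50, the means of 4144 (99.64%) were those of a transcript in the count files within 0.1%, and 0 of these were the transcript named in that place. No gene was therefore taken from the authors' table, and only its numbers of calls are given.

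Estimated counts were summed per gene over 46904 genes and rounded. Testing used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr with a minimum count of 10, and a quasi-likelihood F test in a single fit of all 15 libraries with 12 residual degrees of freedom. It tested 10585 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. Levels are CPM (counts scaled to 1 common library total) with TMM scaling, and errors of log2 fold changes are standard errors from the fit. The common biological coefficient of variation was 0.527. Levels of gas-1 and of the cest-2 genes were also compared by an exact two-sided permutation test of log2 CPM, whose smallest possible p at 5 against 5 is 0.00794.

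A total of 48 gene lists were fixed, covering respiration and mitochondrial stress, detoxification, lipid and intermediary metabolism, defence, proteolysis, protein synthesis, nuclear hormone receptors, and markers of intestine, germline, oocyte, sperm, somatic gonad, muscle, pharynx, neurons, hypodermis and cuticle. Of these, 47 had at least 3 tested members. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. Adjusted p-values of lists are over the 47 lists of a comparison, and counts adjusted over the list alone are given for the lists that the text describes most closely. The members of a list are correlated, so the preset value of 0.01 makes calls easier.

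The text names gas-1 and the cest-2 genes. It also names the 8 largest rises and the 8 largest falls of gas-1 against wild type and of OE against gas-1, and the 5 and 5 largest of OE against wild type. These had to be called, to have a mean log2 CPM of at least 3, and to have all 5 libraries of a group above all 5 of the other. From each list, up to 3 called members with the smallest adjusted p could be named, and the 10 genes with the strongest changes in opposite directions were added. The groups, comparisons, main tests, lists and naming rule were set before the data were examined. So were the alternatives, except those described as chosen later and the covariates in the list tests. Several tests of explanations were also chosen after results were seen, as stated where they are given.

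The comparisons gas-1 against wild type and OE against gas-1 share the gas-1 libraries, which alone gives opposite signs. The number of genes called in both with opposite signs was therefore set beside 20 simulations of unchanged groups and 20 repeats in which separate gas-1 libraries served each comparison. Replicate numbers were tested as pairs. Of the 5 pairs of equal number between gas-1 and wild type, 0 had a correlation of residuals above 0.1, with 1 of 5 for OE and gas-1 and 1 of 5 for OE and wild type, so the samples were treated as unpaired.

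The tests were tried on counts simulated from the mean and spread of each gene and the real library sizes. Known changes were put into the first group of a comparison, in a single draw for each. They covered 67, 67 and 66 genes at 1.5-, 2- and 4-fold, and the genes of the V-ATPase proton pump at 1.5-fold. Genes were drawn independently, so these data held no shifts shared by the genes of a library. edgeR recovered 19.4% of 2-fold and 47% of 4-fold changes in gas-1 against wild type, where 4.3% of its calls were false. In OE against gas-1 it recovered 31.3% and 56.1%, with 1.6% of calls false. In OE against wild type it recovered 16.4% and 48.5%, with 8.2% of calls false. Of the calls of DESeq2 1.42.0, 21.2%, 18.3% and 20.4% were false in the same data, in the same order, out of only 80, 120 and 93 calls. In gas-1 against wild type edgeR called 47 simulated genes, against 2268 in the real data. With so few changed genes the adjusted p is stricter, so these shares may understate recovery where many genes differ. Totals were 12182697 to 45896053 estimated counts per library. At such depths the spread between libraries and not counting error limits the precision for all but weakly expressed genes, and reads carried no molecular identifiers.

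Alternatives were DESeq2 size factors, the DESeq2 Wald test, limma-voom with sample weights, no filter or at least 1 CPM in 5 libraries, a fit of only the groups compared, an offset for effective length, log2(TPM + 0.5) and log2(TPM + 1) with limma, the replicate number as a block, a germline marker covariate, and each library left out. Chosen after seeing the data were a muscle marker covariate, leaving out wild type replicates 1, 2 and 4, removal of ribosomal RNA genes, and keeping 1 of each set of genes with equal counts. Because the libraries keep no strand information, reads of overlapping genes on opposite strands cannot be separated. Nothing was left out of the comparisons except genes under the count filter.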

Results

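Transcripts were counted in 15 libraries of dissected intestines from 5-day-old Caenorhabditis elegans, with 20 intestines per library. The 3 groups of 5 libraries were wild type, gas-1(fc21), a mutant in a subunit of respiratory complex I, and gas-1(fc21) with overexpression of cest-2.2, a member of the carboxylesterase family (gas-1 cest-2.2 OE, or OE). Total estimated counts were 12182697 to 40045140 per wild type library, 12607565 to 17688689 per gas-1 library and 12785262 to 45896053 per OE library. Gene names rest on reading the integers in the count files as line numbers of the deposited transcript map, a reading tested on transcript lengths. Yolk protein genes took 27.4% ± 6.11 of the counts in wild type, 29.1% ± 3.12 in gas-1 and 35.5% ± 6.55 in OE (SD, n = 5 each). The mitochondrial genome took 0.83% ± 0.12, 1.24% ± 0.17 and 1.45% ± 0.33. Log2 CPM of libraries within a group correlated across genes at 0.862 to 0.932 in wild type, 0.855 to 0.925 in gas-1 and 0.891 to 0.926 in OE, and genes are not independent replicates.

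The first question was whether cest-2.2 was overexpressed in these intestines and how gas-1 itself was transcribed. The cest-2.2 transcript (chromosome V, 14171639 to 14175355, WBcel235) stood at 42.2 ± 17.4 CPM in wild type, 56.1 ± 24.2 in gas-1 and 121 ± 42.7 in OE (SD, n = 5 each). The rise from gas-1 to OE was 2.16-fold in the means and 1.11 ± 0.33 on the log2 scale, with an adjusted p of 0.109 over all genes and an exact permutation p of 0.0159 for cest-2.2 alone. With the DESeq2 Wald test, limma-voom or the germline marker covariate the adjusted p of this rise was 0.0373, 0.0209 and 0.0493, and over all alternatives it ran from 0.0209 to 0.251. Against wild type, OE had 2.87 times as much cest-2.2 (log2 1.52 ± 0.34, adjusted p 0.0112, and 0.000288 to 0.173 over the alternatives, the last without wild type replicates 1, 2 and 4). Between gas-1 and wild type cest-2.2 did not differ beyond its spread (log2 0.41 ± 0.33, adjusted p 0.383). The neighbouring cest-2.1 had 20 ± 7.47, 38 ± 16.3 and 44.9 ± 13 CPM and was higher in OE than in wild type (log2 1.16 ± 0.32, adjusted p 0.0327). The gas-1 transcript (chromosome X, 15586786 to 15590397) rose from 67.8 ± 14.4 CPM in wild type to 124 ± 20.8 in gas-1 and 121 ± 28.1 in OE. For gas-1 against wild type the log2 change was 0.87 ± 0.19 (adjusted p 0.00653), all 5 mutant libraries lay above all 5 wild type libraries, and the exact permutation p of 0.00794 was the smallest possible. With the germline marker covariate this change was 0.34 with an adjusted p of 0.546, the highest over its alternatives, of which the lowest was 0.000255.

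**Figure D1:**
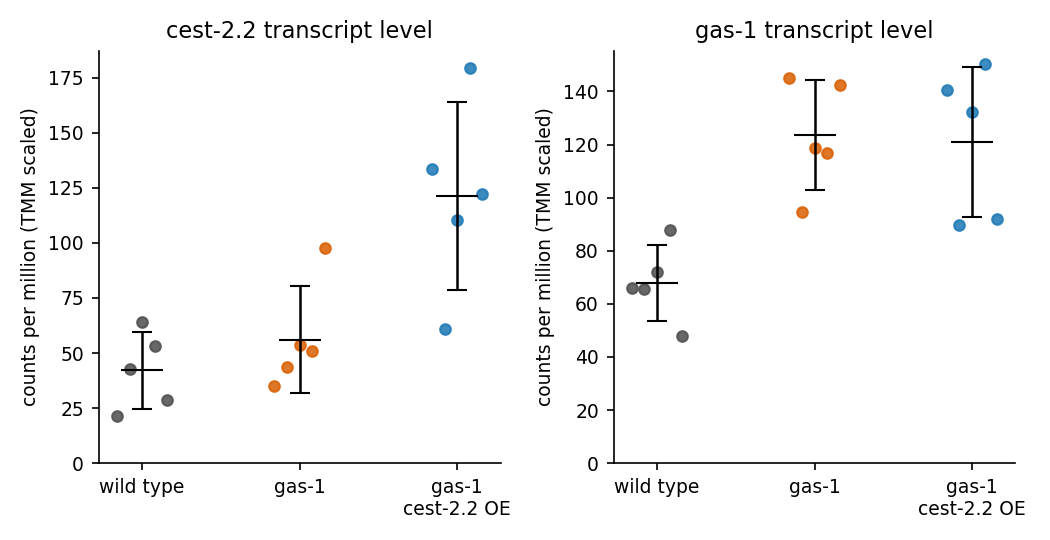
Transcript levels of cest-2.2 and gas-1 in CPM, a point per library and 5 libraries per group, with horizontal bars at the mean and vertical bars of 1 SD. The means of cest-2.2 were 42.2, 56.1 and 121 CPM, and all 5 wild type libraries lay below all gas-1 and OE libraries for the gas-1 transcript.

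The second question was what differed in the intestine between gas-1 and wild type. Among genes with a mean log2 CPM of at least 3 whose groups did not overlap, the steepest rises in gas-1 included B0205.13 (log2 8.96 ± 0.68), from 0.14 to 58.6 CPM, F33H12.7 (6.87 ± 0.70), Y37H2A.14 (6.31 ± 0.69), C49G7.12 (6.27 ± 0.58) and T19C9.8 (6.09 ± 0.52). Also among them were klp-4, a kinesin gene (5.97 ± 0.71), the cytochrome P450 gene cyp-33C8 (5.26 ± 0.68) and cdr-4, of a family named for its response to cadmium (4.33 ± 0.39). Those with the steepest falls were lbp-2, which encodes a fatty acid binding protein (-6.50 ± 0.92), dhs-26, of the short-chain dehydrogenase family (-6.18 ± 1.07), F56A4.3 (-5.97 ± 0.38), T22B7.7 (-5.08 ± 0.80), ule-4 (-4.49 ± 1.14), Y37D8A.2 (-3.65 ± 0.63), ZK813.2 (-3.53 ± 1.00) and C14E2.12 (-3.07 ± 0.33). By the naming rule all 5 libraries of a group lay above all 5 of the other in each of these 16 genes. Their adjusted p ran from 2.52e-07 for F56A4.3 to 0.0219 for ZK813.2. In all, edgeR called 2268 of 10585 genes, 1355 higher and 913 lower in gas-1, of which 1011 and 275 changed at least 2-fold. The number called lower was 303, 320 and 304 without wild type replicate 1, 2 or 5 and 577, 516 and 407 without gas-1 replicate 1, 3 or 5, while 989 to 1179 were called higher in these 6 fits. The groups separated fully in 1683 genes, or 15.9%, where chance gives 0.79%.

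Markers of tissues moved with this comparison. Of 19 tested intestine markers 12 rose and 7 were not called (16 rose adjusted over the list alone), with a median log2 change of 0.98, and pgp-1, a P-glycoprotein transporter gene, rose by 3.53 ± 0.36. Of 24 germline markers 9 fell and 15 were not called (16 fell adjusted over the list alone), with a median of -0.56, among them deps-1 (-0.88 ± 0.17), a P granule gene. Of 18 oocyte and early embryo markers 8 fell and 10 were not called (15 fell adjusted over the list alone), with a median of -0.67, among them rme-2 (-0.81 ± 0.21), the yolk receptor of oocytes. Camera called these 3 lists (adjusted p 7.44e-07, 2.46e-06 and 2.53e-05), and none with an estimated correlation (adjusted p = 0.556 for each). The germline score, a mean log2 CPM, was 6.41 to 6.71 in wild type and 5.58 to 6.45 in gas-1. Of 12 body wall muscle markers 4 fell, including the myosin gene unc-54 (-2.65 ± 0.66), and the list was not called (adjusted p 0.0763). The muscle score was 5.31, 4.46 and 5.92 in wild type replicates 1, 2 and 4, and 2.9 to 4 in all other libraries except OE replicate 1 at 1.92.

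**Figure D2:**
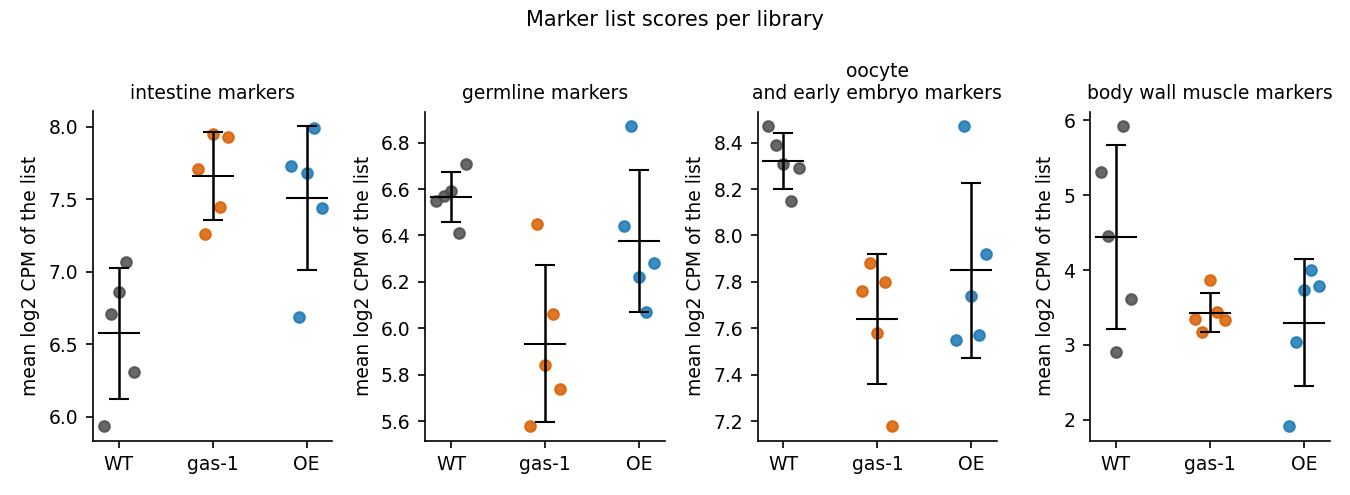
Scores of 4 marker lists, each the mean log2 CPM of the tested members, a point per library and 5 libraries per group (WT, wild type), with the mean and 1 SD. Intestine scores were 5.94 to 7.07 in wild type and 7.26 to 7.95 in gas-1, and muscle scores were highest in 3 wild type libraries.

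In lists of respiratory chain genes most called genes were higher in gas-1. Of 27 nuclear-encoded subunits of complexes II to V, 20 rose and 7 were not called (24 rose and 1 fell adjusted over the list alone), among them the cytochrome c gene cyc-2.1 (log2 1.14 ± 0.17) and the cytochrome oxidase subunit gene cox-5B (0.83 ± 0.14). Of 30 other complex I genes, 10 rose, 1 fell and 19 were not called (14 and 1 adjusted over the list alone), with ndub-11 at 1.2 ± 0.18. Of 9 mitochondrially encoded genes 5 rose, among them ctc-2 (1.07 ± 0.20) and atp-6 (0.81 ± 0.18). Of 13 genes of the mitochondrial unfolded protein response 5 rose and 8 were not called, with clpp-1, a mitochondrial protease gene, at 0.99 ± 0.17 and timm-23, of the protein import machinery, at 0.68 ± 0.14. The gene mdt-22 overlaps clpp-1 by 673 bases on the opposite strand. Camera called the 4 lists (adjusted p 4.63e-08, 7.45e-05, 0.00137 and 0.00556), beside the rise of intestine markers, and each had an adjusted p = 0.556 with an estimated correlation. Their medians were 0.68, 0.42, 0.87 and 0.43, each below the 0.98 of the intestine markers. Of 14 cytosolic heat shock genes edgeR called 0, with 1 at an unadjusted p under 0.05, DESeq2 called 1, and the list had an adjusted p of 0.903.

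In lists of detoxification genes most called genes were higher in gas-1, beside the rise of intestine markers (median 0.98). Of 25 glutathione S-transferases 11 rose (13 adjusted over the list alone), with gst-38 at 3.77 ± 0.41 and gst-6 at 2.16 ± 0.24. Of 59 cytochrome P450s 26 rose and 4 fell, with cyp-13A12 at 4.17 ± 0.42 and cyp-33E2 at 2.82 ± 0.27. Of 54 UDP-glucuronosyltransferases 17 rose and 3 fell, with ugt-62 rising from 140 ± 52.1 to 1337 ± 215 CPM (3.26 ± 0.32) and ugt-19 by 3.63 ± 0.4. Adjusted over the list alone, 29 P450 genes rose and 4 fell, and 20 and 4 of the glucuronosyltransferases. Of 27 other carboxylesterases 13 rose (17 rose and 1 fell adjusted over the list alone), among them cest-8 (3.22 ± 0.37), which shares 629 bases with cest-9.2, and cest-32 (2.53 ± 0.32). Of 162 nuclear hormone receptors 32 rose and 4 fell, with nhr-115 at 2.59 ± 0.27. The methionine sulfoxide reductase gene msra-1 rose by 2.86 ± 0.25, while its list of 23 antioxidant enzymes, 5 of which rose, was not called (median 0.17, or -0.11 with TPM, adjusted p 0.0763). Camera called the 5 other lists at adjusted p of 7.45e-05 or less, and each had an adjusted p = 0.556 with an estimated correlation.

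Among lipid genes, 11 of 19 genes of fatty acid synthesis, desaturation and elongation rose and 1 fell (13 and 1 adjusted over the list alone), including the desaturase genes fat-2 (1.4 ± 0.25) and fat-6 (1.12 ± 0.27) and sbp-1 (1.32 ± 0.27), the homologue of the sterol regulatory element binding protein. Of 22 peroxisomal beta-oxidation genes 7 rose and 1 fell (14 and 1 adjusted over the list alone). The acyl-CoA oxidase gene acox-1.2 fell from 176 ± 46.1 to 22 ± 3.9 CPM (-3 ± 0.23, adjusted p 1.21e-06), and the peroxisomal transporter gene pmp-1 rose by 1.8 ± 0.26. Lysosomal lipase genes lipl-3 and lipl-4 rose by 2.62 ± 0.36 and 3.12 ± 0.5, within a list of 15 lipases of which 5 rose and 1 fell, whose median was -0.44 while camera gave the direction as up (adjusted p 0.4). The lipid binding protein genes lbp-8 and lbp-6 rose by 2.97 ± 0.37 and 1.47 ± 0.23. Of 25 genes of triglyceride and phospholipid synthesis 8 rose and 1 fell, the latter being the glycerol-3-phosphate acyltransferase gene acl-4 (-1.78 ± 0.19). The citrate synthase gene cts-1 rose by 1.18 ± 0.19, and 5 of the 20 genes of its list rose. Camera called the lists of fatty acid synthesis (adjusted p 0.000268), peroxisomal oxidation (0.00082), triglyceride synthesis (0.0356) and the tricarboxylic acid cycle (0.0225), and with an estimated correlation the adjusted p was 0.556 for the first 3 and 0.57 for the last. The medians of these lists were 0.81, 0.79, 0.19 and 0.29, each below the 0.98 of the intestine markers. Of 6 vitellogenin genes edgeR and DESeq2 called 0, with 1 at an unadjusted edgeR p under 0.05.

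In defence and lysosome lists, 27 of 85 C-type lectins rose and 2 fell, with clec-4 rising from 50.3 ± 17.6 to 649 ± 174 CPM (3.69 ± 0.32). Of 12 lysozymes 3 rose, including lys-2 (1.98 ± 0.20), and the saposin-like gene spp-18 rose by 2.17 ± 0.29. Of 23 cathepsin and aspartyl proteases 8 rose and 1 fell, with the cathepsin B gene cpr-4 at 2.63 ± 0.28 and asp-8 at 3.96 ± 0.51. Of 21 subunits of the proton pump V-ATPase 15 rose and 1 fell (17 and 3 adjusted over the list alone), with vha-2 at 0.82 ± 0.17. The autophagy receptor gene sqst-1 rose by 2.18 ± 0.30, with 3 of 24 autophagy genes called. Of 35 histone genes 8 rose and 1 fell, with his-11 at 3.59 ± 0.29, and the median of that list was 0.35, or -0.08 with TPM. Camera called the lists of C-type lectins (adjusted p 1.06e-05), lysozymes (0.0293), proteases (0.000303), V-ATPase (7.45e-05) and histones (0.0133), and each had an adjusted p = 0.556 with an estimated correlation. The medians of these lists were 0.8, 0.39, 0.89, 0.63 and 0.35, each below the 0.98 of the intestine markers. Camera called 23 of 47 lists in this comparison. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and fry called 23. TPM moved the median log2 change of all genes by -0.25, and 41.9% of the 2796 genes it called were higher in gas-1, against 59.7% with counts. With the germline marker covariate 194 genes were called, and without wild type replicates 1, 2 and 4 there were 556, 475 higher and 81 lower. The number was 1329, 1499, 1319, 1505 and 1504 without wild type replicate 1, 2 or 5 or gas-1 replicate 3 or 5. The authors' table called 804 transcripts, 487 higher and 317 lower.

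The third question was what differed between the gas-1 mutant with overexpression of cest-2.2 and the mutant without it. Among genes with a mean log2 CPM of at least 3 whose groups did not overlap, F56A4.3 (chromosome V, 2453414 to 2456147) rose most steeply. It went from 0.89 ± 0.44 to 76.1 ± 24 CPM (log2 6.41 ± 0.39, adjusted p 1.06e-07). It was followed by irld-53 (3.58 ± 0.34), the alcohol dehydrogenase gene adh-1 (3.01 ± 0.54), the lysozyme gene lys-5 (2.79 ± 0.33), clec-209 and F56A4.2, whose counts were equal in every library (2.59 ± 0.25), Y32B12B.4 (2.33 ± 0.21) and Y50D4A.4 (2.3 ± 0.33). The steepest falls within these limits were in the lectin gene clec-190 (-5.58 ± 0.77), Y49E10.16 (-4.09 ± 0.38), C49G7.12 (-2.8 ± 0.47), the P-glycoprotein gene pgp-6 (-2.56 ± 0.49), zip-11, of the bZIP transcription factors (-2.55 ± 0.30), dhs-23 (-2.47 ± 0.38), K02E2.6 (-2.45 ± 0.43) and the aspartyl protease gene asp-12 (-2.42 ± 0.38). By the naming rule the 5 libraries of a group lay above the 5 of the other in each of these 16 genes. Their adjusted p was 0.0125 or less. In all, edgeR called 168 of 10585 genes, 67 higher and 101 lower in OE, and 135 changed at least 2-fold. Without gas-1 replicate 2 there were 226 higher and 154 lower, and with the germline marker covariate 111 and 42, so the balance of directions turned. The number called was 85 and 88 without gas-1 replicate 1 or 3 and 97, 107 and 94 without OE replicate 1, 2 or 5. Those higher were 44, 43, 43 and 32 without wild type replicate 2 or 5, gas-1 replicate 5 or OE replicate 4, and those lower were 62 without OE replicate 3. The groups separated fully in 398 genes, or 3.76%, where chance gives 0.79%.

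Of 27 genes of complexes II to V, 30 of complex I and 9 encoded in mitochondria, edgeR called 0, with 3, 2 and 2 at an unadjusted p under 0.05, and DESeq2 called 0, 1 and 0. Their medians were -0.12, -0.01 and 0.37, and the lists had adjusted p of 0.147, 0.633 and 0.0814. Defence genes moved both ways. Of 12 lysozymes, lys-4 (1.54 ± 0.27) and lys-5 rose and lys-2 fell (-1.14 ± 0.19), while 2 of 85 C-type lectins rose and 5 fell, including clec-4 (-1.49 ± 0.29). Saposin-like spp-10 rose by 1.08 ± 0.24, irg-4, a gene induced by infection, fell (-2.17 ± 0.29), and dod-24 rose by 1.39 ± 0.25. Among lipid genes, dgat-2, a diacylglycerol acyltransferase gene, fell from 12.2 ± 1.98 to 5.13 ± 1.65 CPM (-1.26 ± 0.27), and lbp-8 fell (-1.52 ± 0.35). Of 19 genes of fatty acid synthesis and desaturation, 22 of peroxisomal beta-oxidation and 15 lipases edgeR called 0, with 0, 4 and 4 at an unadjusted p under 0.05, and DESeq2 called 0, 1 and 3. The metallothionein gene mtl-2 fell (-1.21 ± 0.27), lea-1 rose by 1.75 ± 0.26, msra-1 fell (-1.43 ± 0.24), and lgg-1, the autophagy gene homologous to yeast ATG8, fell (-0.93 ± 0.17).

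Camera called 9 lists. Lower in OE than in gas-1 were cytosolic ribosomal proteins (median -0.28, adjusted p 9.16e-12), histones (-0.66, 2e-06, 3 of 35 lower), cytochrome P450s (-0.48, 0.000112, 2 of 59 lower), cuticle collagens (-1.14, 0.000803, 1 of 41 lower), nuclear hormone receptors (-0.37, 0.000909, 1 of 162 lower), UDP-glucuronosyltransferases (-0.2, 0.00279, 3 of 54 lower) and the proteasome (-0.2, 0.00822). Of 80 ribosomal protein genes and 33 proteasome genes edgeR called 0, with 20 and 3 at an unadjusted p under 0.05, and DESeq2 called 1 of each list. Examples were cyp-33E2 (-1.23 ± 0.25), ugt-41 (-2.08 ± 0.42) and his-11 (-1.32 ± 0.27). Higher were germline markers (median 0.48, adjusted p 6.94e-06) and pharynx markers (1.18, 0.0133). Of 24 germline genes edgeR called 0 over all genes, 14 had an unadjusted p under 0.05 and 10 rose adjusted over the list alone, and DESeq2 called 0, while of 9 pharynx genes both tools called 0, with 0 at an unadjusted p under 0.05. With an estimated correlation the adjusted p = 0.583 for histones and 0.873 for each of the 8 others. At that setting camera called 0 lists with 1 at an unadjusted p under 0.05, and fry called 0 with 5. TPM moved the median of all genes by -0.13, and 15.2% of the 310 genes it called were higher in OE, against 39.9% of 168. The number of genes called was 514 with DESeq2. The authors' table called 528 transcripts, 241 higher and 287 lower.

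The fourth question was whether genes moved back toward their wild type level with overexpression. Of the 168 genes that differed between OE and gas-1, 80 were higher in gas-1 than in wild type and lower again in OE, 42 were lower in gas-1 and higher again in OE, and 3 had moved in the same direction in both comparisons. Independent lists would give 18.7 genes of opposite and 17.3 of equal direction. The 80 genes included zip-11, at 2.78 ± 0.71, 27 ± 4.3 and 4.61 ± 2.06 CPM in wild type, gas-1 and OE, and clec-70, K02E2.6, F21C10.9, C49G7.12 and clec-190, with smaller absolute log2 changes of 2.33 to 2.8. The 42 genes included F56A4.3, irld-53 and the pair F56A4.2 and clec-209, at 1313 ± 378, 237 ± 57.6 and 1433 ± 365 CPM. Of the genes of both kinds, 22 were still called between OE and wild type. Of the 80 and 42 genes, 5 only repeated the counts of another gene in every library. Across genes the 2 log2 changes correlated at -0.465 (Pearson) and -0.482 (Spearman), but genes are not independent replicates and both comparisons share the gas-1 libraries. Simulated unchanged groups gave -0.53 to -0.47 and 0 genes called in both. No gene was changed in them, so that 0 was fixed by the setting and is no baseline for the number of genes called here. With separate gas-1 libraries for each comparison the correlation was -0.28 to -0.1, with 14 to 91 genes called in opposite directions and 0 to 5 in the same direction. Germline markers moved alike, at a median of -0.56 and then 0.48. The number of genes was 66, 295 and 65 without gas-1 replicate 1, 2 or 3, and 80, 75, 80 and 68 without OE replicate 1, 2, 3 or 5. It was 354 with DESeq2, 195 with limma-voom, 222 with TPM (199 higher and then lower, 23 lower and then higher) and 52 with the germline marker covariate (24 and 28). The 42 genes became 25, 25 and 21 without wild type replicate 1, 2 or 5, 20, 22 and 25 without gas-1 replicate 1, 3 or 5, and 27, 25, 20 and 23 without OE replicate 1, 2, 4 or 5, and they became 173 without gas-1 replicate 2.

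**Figure D3:**
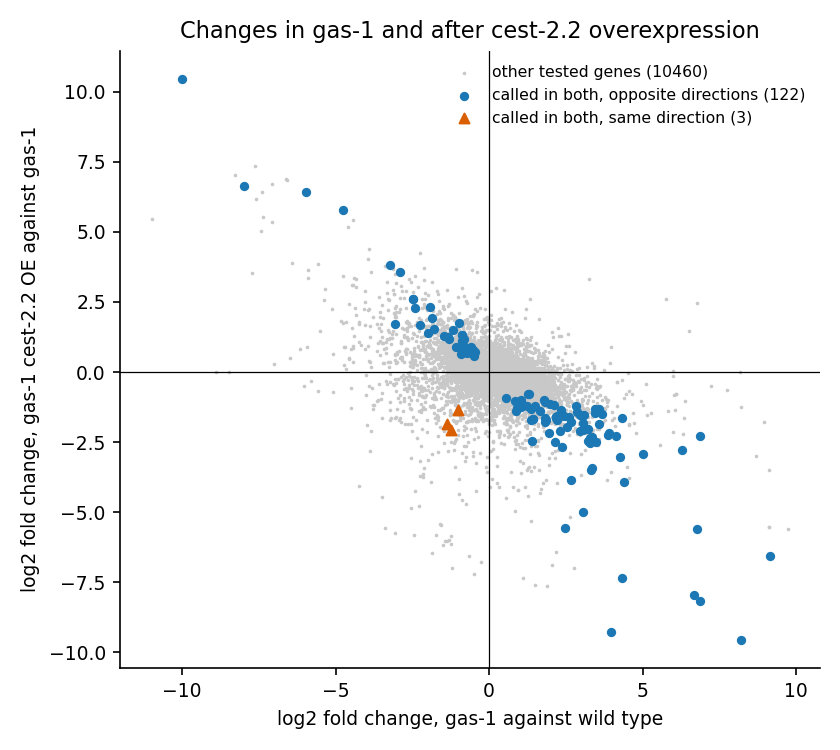
Log2 fold changes of 10585 genes, gas-1 against wild type on the horizontal axis and OE against gas-1 on the vertical axis, a point per gene, with genes called in both in colour. Of the genes called in both, 80 rose and then fell, 42 fell and then rose and 3 moved alike, and points far from 0 on both axes include genes with counts near 0 in a group.

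Several of the lost and regained genes lay close together near the left end of chromosome V. Between 2345676 and 2502426, a stretch chosen after its values were seen, 18 genes were tested, 11 were lower in gas-1 than in wild type and 8 of these were higher again in OE. In 17 of the 18 the mean CPM in gas-1 was below that of both other groups, the exception being F56A4.5, which was higher in gas-1. The median log2 change was -1.76 from wild type to gas-1 and 1.86 from gas-1 to OE. The chemoreceptor gene srbc-15 had 0 counts in all 5 gas-1 libraries, against 6.66 CPM in wild type and 9.17 in OE, which at a floor of 3 counts over the group was at least 168-fold lower than wild type. Genes in 5 sets in this stretch had equal counts in every library, so their reads were divided between copies. The 18, 11 and 8 genes therefore hold fewer separate measurements. In the 100 kb on either side, 22 tested genes had medians of 1.01 and -0.47, and 0 were lower in gas-1 and higher in OE. The ends of the stretch were set at genes that moved in this way, so that 0 is partly built in.

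**Figure D4:**
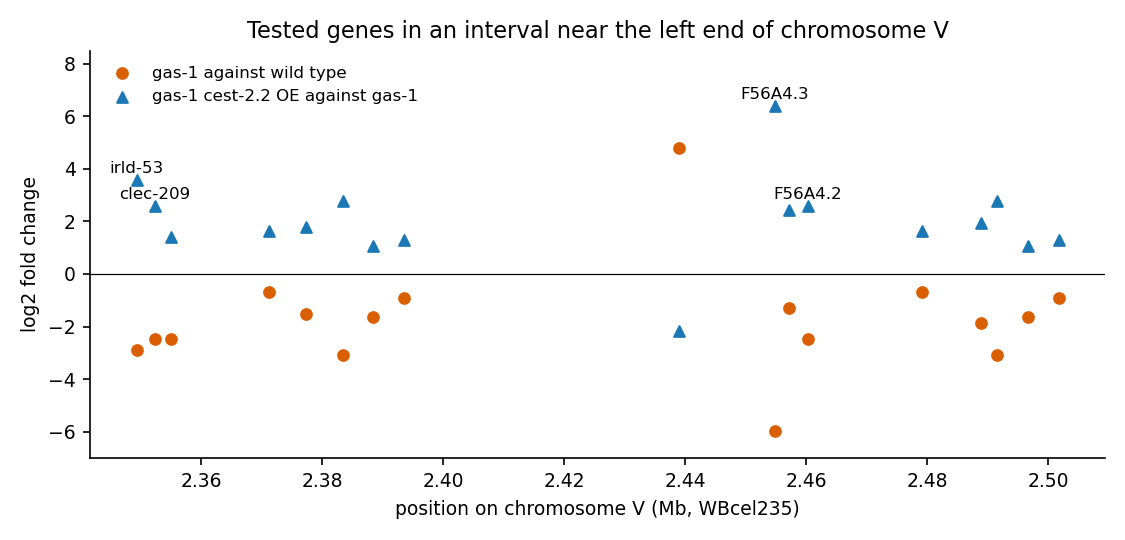
Log2 fold changes of 17 tested genes by position on chromosome V in Mb, gas-1 against wild type as circles and OE against gas-1 as triangles, with srbc-15 left out because its gas-1 counts were 0. In this stretch F56A4.3 changed by -5.97 and then by 6.41, and equal values at separate positions are copies that share reads.

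The last question was what still differed from wild type in the overexpressing mutant. Steep rises over wild type were B0205.13 (log2 7.17 ± 0.66), klp-4 (5.83 ± 0.70), T19C9.8 (5.29 ± 0.51), asp-8 (4.86 ± 0.53) and F33H12.7 (4.59 ± 0.65), and steep falls were dhs-26 (-5.36 ± 1.02), T22B7.7 (-4.46 ± 0.78), Y49E10.16 (-3.77 ± 0.37), F13D11.4 (-3.33 ± 0.55) and ugt-41 (-3.32 ± 0.44). By the naming rule the libraries of the groups did not overlap in these 10 genes. In all, 988 genes were called, 751 higher and 237 lower, and 679, or 6.41%, separated fully where chance gives 0.79%. There were 487 higher and 84 lower without wild type replicate 1, 630 higher of 752 without wild type replicate 2, and 465 and 99, 1258 and 372, and 413 and 99 without OE replicate 1, 2 or 4. The genes on the mitochondrial genome rose in 7 of 9 cases, with ctc-1 from 3567 ± 465 to 9310 ± 2371 CPM (1.38 ± 0.23), and 12 of 27 genes of complexes II to V rose (22 adjusted over the list alone). The acid lipase gene lipl-5 rose by 1.97 ± 0.28, asah-2, an acid ceramidase gene, by 2.04 ± 0.27, and the yolk gene vit-2 by 1.16 ± 0.33, with 2 of 6 vitellogenins called. Of 12 lysozymes 6 rose, including lys-4 (2.04 ± 0.27) and lys-5 (2.45 ± 0.32). Of 23 cathepsin and aspartyl proteases 12 rose and 2 fell, including cpr-4 (1.99 ± 0.27). Intestine markers rose in 11 of 19 cases. Of 24 germline markers edgeR called 0, with a median of -0.18 and 2 at an unadjusted p under 0.05, and DESeq2 called 0.

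Of 41 cuticle collagens 10 were lower (19 lower adjusted over the list alone), and of 12 body wall muscle markers 4 were lower. Without wild type replicates 1, 2 and 4, whose muscle scores were high, the muscle list turned direction and was not called (camera adjusted p 0.889). The hypodermis marker col-19 stood at 158 ± 136 CPM in wild type and 29.6 ± 28.8 in OE (-2.42 ± 0.73, adjusted p 0.0474), and it overlaps ZK1193.2 by 985 bases. Camera called 25 lists, 20 higher and 5 lower, with adjusted p of 1.49e-07 for intestine markers, 2.52e-07 for proteases, 7.27e-07 for the mitochondrial genome, 8.65e-08 for complexes II to V, 4.16e-06 for lysozymes, 1.51e-05 for collagens, 0.00983 for muscle and 0.0185 for vitellogenins. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and the lowest adjusted p = 0.48, while fry called 16. TPM moved the median of all genes by -0.38, and 33.7% of the 1399 genes it called were higher in OE, against 76% with counts. The number of genes was 1535 with DESeq2, 2070 with limma-voom, 644 with the 2 groups alone, and 144 without wild type replicates 1, 2 and 4. The authors' table called 409 transcripts, 212 higher and 197 lower.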

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

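The muscle marker covariate, leaving out wild type replicates 1, 2 and 4, the tests on chromosome V of a strain difference and of reads moving between copies apart from clec-209 and F56A4.2, the tests of the size of changes against marker medians and the test of an intestine share for genes lower again in OE were chosen only after their results were seen.

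Of 423 groups of 5 libraries tested over the values given here, 29 (6.9%) held a library whose gap to its nearest neighbour exceeded 0.71 of the range of the group, where chance gives about 1 in 20, or 21.1. OE replicate 2 accounted for 12 of these values, which may not be separate outliers. Its scores of tissue markers, not flagged by this rule, also stood apart from the other OE libraries. Its intestine score was 6.69 against 7.44 to 7.99, its germline score 6.87 against 6.07 to 6.44 and its oocyte score 8.47 against 7.55 to 7.92. Its score of V-ATPase genes was 5.87 against 6.36 to 6.48 in the other OE libraries, and its score of nuclear hormone receptors 0.95 against 1.81 to 2.07. Its log2 CPM was low for cpr-4 (9.89 against 11.05 to 11.26), dgat-2 (1.53 against 2.51 to 2.8), F21C10.9 (3.65 against 5.14 to 5.64), fat-2 (9.92 against 10.79 to 11.13) and lipl-4 (1.93 against 3.17 to 3.53). It was low as well for lys-4 (11.93 against 12.87 to 13.19), mtl-2 (7.43 against 8.54 to 8.95), pgp-6 (1.09 against 2.78 to 3.03) and vha-2 (7.75 against 8.4 to 8.44), and high for deps-1 (7.22 against 6.5 to 6.7). OE replicate 5 had 45896053 counts against 12785262 to 19437969, and the mitochondrial genome took 2.03% of them against 1.25% to 1.41%. OE replicate 3 had a collagen score of 3.81 against 1.47 to 1.89 and unc-54 at 6.08 against 3.36 to 4.15, and OE replicate 4 had a histone score of 0.73 against 1.5 to 1.66.

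In gas-1 replicate 2 the score of complexes II to V was 6.1 against 6.42 to 6.51 in the other gas-1 libraries, with cyc-2.1 at 7.17 against 7.51 to 7.61, fat-6 at 7.88 against 8.71 to 9.01 and lbp-6 at 6.59 against 7.16 to 7.31. The germline score of that library, not flagged by this rule, was 6.45 against 5.58 to 6.06. In gas-1 replicate 3, clpp-1 was at 4.54 against 4.05 to 4.14. In gas-1 replicate 4, lbp-2 was at -0.06 against 1.45 to 2.02. In gas-1 replicate 5, C14E2.12 was at 0.41 against 1.28 to 1.57 and dgat-2 at 4.02 against 3.51 to 3.63. Among wild type libraries, replicate 1 had an antioxidant score of 3.6 against 3.38 to 3.43 and lipl-4 at -0.61 against 1.05 to 1.64. Wild type replicate 2 had a pharynx score of -2.23 against 1.36 to 2.35, and wild type replicate 5 an autophagy score of 3.32 against 3.7 to 3.82.

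Other splits of the same 10 libraries, 5 against 5, were fitted in the same way, 100 per comparison with the real one included. For gas-1 against wild type 1 split gave as many genes as the real 2268, with 897 in the highest other. For OE against gas-1 it was 1 split for 168 genes, with 4 in the highest other. This argues against chance for these numbers, though 1 of 100 was the smallest share the splits could give. The 80 and 42 genes of opposite direction were reached by 1 split, with 1 gene in the highest other, but they are part of the 168 and this adds no evidence of its own. For OE against wild type 2 splits gave 988 genes or more, which argues against chance less strongly. The highest other gave 1957, more than the real grouping, and kept 4 of the 5 OE libraries together. Splits that kept as many together also gave 0, 193 and 897 genes, so being close to the real split does not account for the 1957. The real grouping was therefore not the strongest contrast among these libraries. For the number of gene lists chance cannot be excluded: 20 splits gave 23 lists or more, 67 gave 9 or more and 26 gave 25 or more, with 34, 35 and 38 in the highest others. Without 1 library the number of genes was 1319 to 2489, 85 to 380 and 512 to 1630, with the lowest values without wild type replicate 5, gas-1 replicate 1 and OE replicate 4.

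Between wild type and gas-1, 1355 genes rose and 913 fell while intestine markers rose and germline and oocyte markers fell, with 303, 320 and 304 falls without wild type replicate 1, 2 or 5 and 577, 516 and 407 without gas-1 replicate 1, 3 or 5. Muscle RNA in wild type replicates 1, 2 and 4 is argued against as the whole cause of the falls. Cuticle RNA had no test of its own, and the collagen score was 5.7, 4.45 and 5.33 in these libraries, against 0.82 and 3.24 in wild type replicates 3 and 5. The median within-group correlation of the lower genes with the muscle score differed from that of all tested genes by -0.202. With the muscle marker covariate 76.7% were still called lower, just above the bound set for this test. Without wild type replicates 1, 2 and 4 only 8.9% of the lower and 32.7% of the higher genes were still called. Fewer wild type libraries remained in that fit, so this loss cannot decide. Falls numbered 303, 320 and 980 without wild type replicate 1, 2 or 4, and 304 without replicate 5, whose muscle score was only 3.62. A part of muscle RNA in the falls, and cuticle RNA, stay open. A lower share of gonad RNA and a higher share of intestine RNA in the gas-1 libraries stay open as candidate explanations, since the lower genes followed the germline score within groups by 0.48 more than all tested genes and the higher genes the intestine score by 0.73 more (permutation p of 1e-04 each, the smallest that permutations could give). Of the higher genes 106 (7.8%) lay above a log2 bound of 1.98, the intestine marker median plus 1, even less 2 standard errors. Of the lower genes 69 (7.6%) lay below -1.67, the oocyte marker median less 1, even with 2 standard errors added. Both shares lay between the limits set for either outcome. For the higher and lower genes as a whole, a share of tissue and another effect therefore cannot be told apart. The genes beyond the bounds, picked by size, changed by more than a tissue shift of the marker medians alone would give. With the germline covariate 194 genes were called, 176 of them among the 2268, but that score itself differed between the groups, and an effect of the mutation on transcription in the intestine was not tested apart from it. Another difference between the strains stays open as well and was not tested apart from the mutation.

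Toward wild type, 80 genes were lower again in OE than in gas-1 and 42 higher again, with fewer genes in all without gas-1 replicate 1 or 3 (66 and 65) or OE replicate 1, 2, 3 or 5 (80, 75, 80 and 68) and more without gas-1 replicate 2 (295, with 173 higher again). The sharing of gas-1 libraries by both comparisons is argued against as the whole cause, since with separate libraries the covariance of the log2 changes was -0.502 to -0.21, below the -0.198 to -0.156 of simulated unchanged groups with shared libraries. A lower intestine share in OE is argued against as the whole cause for the 80 genes, since the intestine markers had a median of only -0.08 from gas-1 to OE (SD 0.51). These genes had a median of -1.7, but they were picked for falling in OE, so that gap is partly built in and adds no evidence of its own. Within groups these genes followed the intestine score by 0.538 more than all tested genes (permutation p 3e-04), so a part stays open. A lower gonad share in gas-1 than in both other groups may contribute to the 42 genes, which followed the germline score within groups by 0.32 more than all tested genes (permutation p 0.0013). The germline markers rose by a median of 0.48 and these genes by 1.22, a gap that is partly built in because these genes were picked for rising. An effect of cest-2.2 overexpression, or another difference between the strains, stays open and was not tested apart from the groups.

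Near the left end of chromosome V, 8 of 18 tested genes were lower in gas-1 and higher again in OE, with copies of equal counts each counted. Reads moving among the copies summed here are argued against apart from clec-209 and F56A4.2, since without this pair the counts summed over these genes, the irld genes and the genes of the same clones differed by -1.73 on the log2 scale between gas-1 and wild type and by -2.13 between gas-1 and OE. Copies outside that sum, such as srbc genes elsewhere, were not covered. The sum also holds genes picked for falling in gas-1, so a lower value is partly built in. For the pair, which made up 94.4% of the summed counts and so most of the -2.4 found with it, reads moving to other lectin genes and a real loss cannot be told apart, since the sum over all 264 clec genes differed by 0.38 from wild type and by -0.51 from OE. A candidate explanation is a difference of copy number or sequence between the strains. Beyond the genes seen first 3 of 19 tested genes from 2.3 to 2.5 Mb moved in this way, against 35 of 10561 elsewhere (Fisher's exact p 3.98e-05). That range was chosen around genes already seen to move, and some of its genes share reads. The p-value treats genes as independent and so cannot decide for this explanation. Genome sequence of the strains was not analysed here, 34 of the 42 genes lay outside the stretch, and an effect of the mutation or of overexpression on these genes stays open.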

How the results depend on the processing

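The muscle marker covariate, leaving out wild type replicates 1, 2 and 4, removal of ribosomal RNA genes, keeping 1 of each set of genes with equal counts, and covariates in the list tests were chosen only after the results were seen. With DESeq2 size factors, no filter, at least 1 CPM in 5 libraries, the effective length offset, no ribosomal RNA genes or 1 gene of each equal set, the counts of genes were 1903 to 2299 for gas-1 against wild type, 144 to 190 for OE against gas-1 and 927 to 1001 for OE against wild type. The levels of cest-2.2 and gas-1 kept their direction and side of the threshold in these 6. For the changes below the cause was not tested unless stated.

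With the DESeq2 Wald test the counts were 514 (OE against gas-1), 1535 (OE against wild type) and 354 of opposite direction, and the rise of cest-2.2 from gas-1 to OE passed at 1.08. With limma-voom they were 2070 (OE against wild type) and 195, cest-2.2 passed at 1.31, and gas-1 turned to 0.03 from gas-1 to OE. In simulated data with few changed genes 21.2% and 18.3% of DESeq2 calls were false. With only the groups compared OE against wild type gave 644, with fewer libraries in the fit. With log2(TPM + 0.5) the counts were 310 (OE against gas-1) and 222 of opposite direction, with log2(TPM + 1) 349 and 257, and with TPM and no filter 610 (OE against wild type). The change of gas-1 from wild type to OE no longer passed at 0.454, 0.451 and 0.454, and that of clpp-1 was -0.004 in each. With the replicate block, which pairs libraries by number, 102 genes were called in OE against gas-1 and 80 in opposite directions, while residuals of paired libraries correlated at only -0.039 to 0.272 for OE and gas-1.

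With the germline covariate 194 genes (gas-1 against wild type) and 52 of opposite direction were called, and OE against gas-1 turned to 111 higher and 42 lower. In gas-1 against wild type cest-2.2 turned to -0.28 and gas-1 no longer passed at 0.34. In OE against gas-1 cest-2.2 passed at 1.53 and gas-1 turned to 0.33. Lists called were 11 and 21, and 6 lists turned direction, not called: in gas-1 against wild type peroxisomal oxidation (adjusted p 0.685), triglyceride synthesis (0.798), lysozymes (0.915) and proteases (0.915), and in OE against gas-1 UDP-glucuronosyltransferases (0.574) and nuclear hormone receptors (0.709). Of named genes 51 of 134 kept their call in gas-1 against wild type and 28 of 46 in OE against gas-1. The covariate differs between the groups, which takes up part of each comparison. With the muscle covariate OE against wild type gave 636 genes. Without wild type replicates 1, 2 and 4, which leaves fewer samples, 556 and 144 genes differed from wild type in gas-1 and OE, cest-2.2 and gas-1 in OE against wild type no longer passed at 1.37 and 1.01, and muscle markers turned direction (adjusted p 0.889). With an estimated correlation camera called 0, 0 and 0 lists, and fry called 0 in OE against gas-1 and 16 in OE against wild type.

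With each library left out in turn, gas-1 against wild type gave 1319 to 2489 genes and 22 to 26 lists. OE against gas-1 gave 85 to 380 genes and 8 to 15 lists, and OE against wild type 512 to 1630 and 24 to 28. The lowest counts were without wild type replicate 5, gas-1 replicate 1 and OE replicate 4, and the highest without wild type replicate 4, gas-1 replicate 2 (226 higher and 154 lower) and OE replicate 2. From 65 to 295 genes had opposite directions, the lowest without gas-1 replicate 3 and the highest without gas-1 replicate 2. For cest-2.2 the log2 change was 0.15 to 0.61 in gas-1 against wild type, 0.91 to 1.37 in OE against gas-1 and 1.35 to 1.73 in OE against wild type. For gas-1 it was 0.8 to 1.02, -0.15 to 0.05 and 0.76 to 0.98, and the value for OE against gas-1 was 0.033, 0.035 and 0.053 without gas-1 replicate 1, OE replicate 2 or OE replicate 5. In simulated data with few changed genes 19.4% of 2-fold changes were recovered in gas-1 against wild type, so genes without a call are not shown to be unchanged. Counting error limits weakly expressed genes, and the spread between libraries limits the others.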

Other observations

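The lists below were tested in the same way as the others, and no test here was chosen after its result was seen. Between wild type and gas-1 the cytosolic ribosomal protein list was called (median 0.33, adjusted p 7.43e-09), with 3 of 80 genes higher, and the sphingolipid list (median 0.46, adjusted p 0.0248), with 7 of 18 higher and 2 lower, each at an adjusted p of 0.556 with an estimated correlation. Camera did not call mitochondrial beta-oxidation (adjusted p 0.778), acyl-CoA synthetases (0.668), lipid binding proteins (0.133), glycolysis and gluconeogenesis (0.372), the propionate shunt (0.668) or the methionine and folate cycle (0.196). It did not call the unfolded protein response of the endoplasmic reticulum (0.297), saposin-like proteins (0.0605), pathogen response genes (0.196), genes activated by DAF-16 (0.196), autophagy (0.903), the proteasome (0.133) or mitochondrial ribosomal proteins (0.946). Markers of sperm (0.905), somatic gonad (0.862), pharynx (0.467), neurons (0.868), hypodermis (0.862) and cuticle collagens (0.346) were not called. The median and the direction of the test differed in sign for neurons (median -0.43, direction up), autophagy (median -0.1, direction up) and mitochondrial ribosomal proteins (median 0.01, direction down). The mean log2 change differed in sign from the median for acyl-CoA synthetases (-0.32 and 0.31), lipid binding proteins (-0.08 and 0.7), lipases (0.14 and -0.44), autophagy (0.21 and -0.1) and cytosolic heat shock genes (0.1 and -0.04).

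Between wild type and OE camera called further lists. Higher were complex I (median 0.35, adjusted p 2.01e-05), the mitochondrial unfolded protein response (0.4, 0.00158), glutathione S-transferases (0.81, 6.29e-05), cytochrome P450s (0.73, 0.00114), UDP-glucuronosyltransferases (0.54, 0.0172), other carboxylesterases (0.98, 3.67e-06), peroxisomal oxidation (0.78, 0.00114) and fatty acid synthesis (0.83, 1.97e-05). Also higher were sphingolipid genes (0.69, 0.00114), the tricarboxylic acid cycle (0.36, 0.000382), C-type lectins (0.86, 4.03e-05), saposin-like proteins (0.94, 1.5e-05), V-ATPase (0.37, 0.0023) and nuclear hormone receptors (0.43, 0.00244). Lower were the proteasome (-0.33, 1.18e-05), oocyte markers (-0.46, 0.000356) and hypodermis markers (-1.84, 0.0493). With an estimated correlation these lists had adjusted p of 0.48 to 0.663. With TPM the medians of complex I, the tricarboxylic acid cycle, V-ATPase and nuclear hormone receptors were -0.03, -0.01, -0.02 and -0.04, beside a shift of -0.38 in the median of all genes. The mean log2 change of UDP-glucuronosyltransferases was -0.15, opposite in sign to the median.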
